A study of Mus musculus with 3 samples.

How the data were processed

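RNA from 4T1 mouse mammary cancer cells was labelled with biotin and hybridised to Affymetrix Mouse Genome 430 2.0 arrays, per the labels' protocols. The 3 arrays were 1 each for regular medium, MSC-conditioned medium and co-culture with MSCs, and the groups were taken from the labels. The source of the MSCs and the way the 4T1 cells were isolated are not given in the sources used here. The values were used as deposited, as linear intensity values made with MAS5, per the submitters' processing notes, whose version and scaling target are not given in the sources used here. MAS5 combines the probes of a probe set into 1 signal and scales each array to a common level. The 2%-trimmed means of the arrays were 497.3, 497.2 and 496.6, so no further scaling was applied. The highest signals were 42425, 43954 and 38152.

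Of the 45037 probe sets, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none, and the last groups are unnamed here. Symbols were updated through the gene ID for 34741 probe sets, giving 18193 genes. For 9010 genes with more than 1 probe set, the probe set with the highest mean signal over the 3 arrays stood for the gene. Probe sets whose names mark possible cross-hybridisation were kept, and an alternative left them out.

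Signals below the pooled 40th percentile of all probe sets, 42.4, were set to that floor before log2 was taken. The floor is a level and not a detection call. A gene at the floor on the dimmer array has a lower bound, written as at least N-fold. A gene counted as higher or lower when its signals differed at least 2-fold and the brighter signal was at or above the pooled 60th percentile, 149.3. Because each group had 1 array, no test was run, and the number of arrays limits the precision. Alternatives covered other scalings, floors, signal filters, probe set choices and 1.5-fold and 3-fold rules.

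A total of 29 gene lists were fixed before the data were examined, along with the comparisons, the rule for named genes and the alternatives. For each list the median log2 difference was taken over measured members, those reaching 149.3 on at least 1 array. Its percentile among 10000 random lists of the same size, matched on mean signal in 10 bins, was given as a description of these arrays. Of the 29 lists, 25 had at least 5 measured members, and the other 4 give member values only. A further 7 lists were added after the values were seen and appear in the closing section only.

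Named genes were, for each comparison, the 10 with the largest difference in each direction (5 for co-culture against conditioned medium) among genes above the floor on both arrays. The 3 largest in each direction with the dimmer array at the floor were added, and up to 4 members of each list with the largest differences. Predicted genes with clone, locus or RIKEN names were passed over. Ifit2 and Stat2 in the interferon list, Cd74 in the antigen presentation list and the genes marked as chosen after their values were seen fall outside this rule. Genes with another bright probe set that differed in direction by over 1.5-fold are named with that fact.

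Technical scatter per array was taken from the disagreement between probe sets of the same gene, over 5839 pairs. This scatter also holds differences between transcript forms and, for co-culture, real effects, but no variation between separate cultures. Unchanged arrays were simulated 100 times with it, including for comparisons that share an array. The overlap and covariance were also simulated under the alternatives that moved them, with the same scatter, after their values were seen. The planned ratios of 3' to 5' control signals as a sign of RNA quality were not analysed here, and the share of probe sets at the floor was given in their place.

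The procedure was tested on simulated data for co-culture against regular medium with 18193 genes, of which 200 were changed, 50 at each fold. With the narrower scatter, that of conditioned medium against regular medium, it called 48 of 50 genes changed 3-fold, 47 of 50 changed 4-fold, 48 of 50 changed 8-fold, 0 of 50 changed 1.5-fold and 10 of 17993 unchanged genes. With the wider scatter, that of co-culture against regular medium, it called 45, 46, 49 and 7 of 50 in the same order and 192 of 17993 unchanged genes. With the narrower scatter, of 100 unchanged lists 5 lay outside the central 95% of random lists, as did 20 of 20 shifted lists. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.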

Results

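4T1 is a mouse mammary carcinoma cell line. RNA from 4T1 cells was measured on 3 Affymetrix Mouse Genome 430 2.0 arrays, with 1 array for each culture condition. In the regular-medium condition the cells were cultured with regular medium, for a time the labels do not give, so culture time may differ from the other conditions. In the conditioned-medium condition they were grown for 1 week in medium conditioned by MSCs, an abbreviation usually read as mesenchymal stem or stromal cells. In the co-culture condition they grew for 1 week in contact with MSCs and were then isolated from the mixed culture. Each array gave a MAS5 signal for 45037 probe sets. The median signal was 79.8 in regular medium, 71.6 in conditioned medium and 72.5 in co-culture, and 38.0%, 41.4% and 40.7% of probe sets lay at or below the floor of 42.4 used here. Of 18193 named genes, 9452 reached a signal of 149.3 on at least 1 array and are called measured. There were no replicates, so every difference below compares 2 arrays and has no replicate error, test or p-value. A gene is called higher or lower when its signals differed at least 2-fold and the brighter one was 149.3 or more.

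Contact co-culture with MSCs was compared with regular medium to see how the 4T1 transcripts differed after 1 week of contact and the isolation that followed it. Genes induced by interferon had many of the largest differences above regular medium, and the measured genes of cholesterol synthesis all lay below it. Usp18, a protease that removes ISG15 and restrains interferon signalling, was 58.9-fold higher in co-culture, with a signal of 3248 against 55.1. Idi1, the isopentenyl diphosphate isomerase of the mevalonate pathway, was 8.23-fold lower, with 779.3 against 6415. Of 9393 genes with a bright signal on at least 1 of these 2 arrays, 546 were higher and 259 were lower, and 94 and 21 of them differed at least 4-fold. Unchanged arrays simulated with the scatter between probe sets of the same gene gave 156 to 214 such genes over 100 simulations, against the 805 observed, and hold no variation between cultures.

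Of the 22 measured interferon response genes, 20 were higher in co-culture, none was lower, and the other 2 were Ifit2 and Stat2 with log2 differences of 0.45 and 0.86. The median log2 difference of the list was 2.75, a median fold of 6.74, with an interquartile range over genes of 2.08 to 3.34. This lay above all 10000 random lists of the same size and mean signal. Oasl2, a member of the oligoadenylate synthetase family, was 18.3-fold higher, Ifit1, which binds viral RNA, was 16.8-fold higher, and Rtp4, an interferon-induced chaperone of receptor transport, was 14.7-fold higher. Xaf1, an interferon-induced promoter of cell death, was 12.6-fold higher. Oas3 was at least 12.7-fold higher and Zbp1, a sensor of nucleic acids, at least 8.37-fold higher, each from a signal at the floor in regular medium. Irgm2 and Igtp, immunity-related GTPases induced by interferon, were 24.6-fold and 16.8-fold higher. On the same array the MSC and fibroblast markers had a median log2 difference of 0.61. Of the 10 measured markers, 7 were already bright in regular medium, so this median is not a measure of MSC RNA alone.

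**Figure D1:**
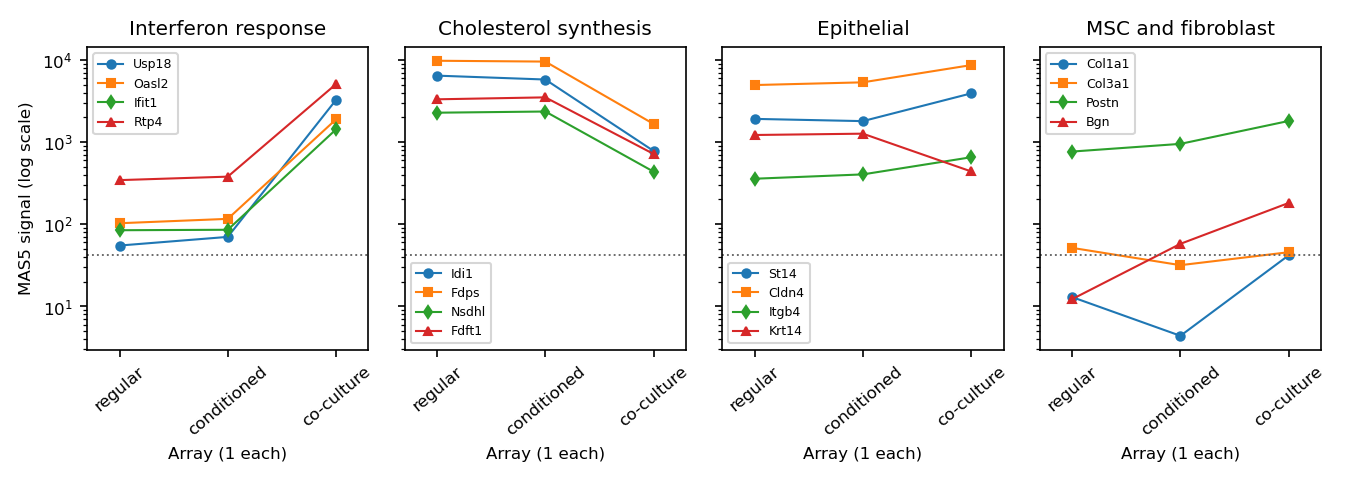
MAS5 signal (vertical axis, log scale) on the 3 arrays (horizontal axis, 1 array per condition) for 4 genes from each of 4 lists, with the floor of 42.4 as a dotted line. Usp18 was at 55.1 in regular medium, 70.2 in conditioned medium and 3248 in co-culture, Fdps was at 9734, 9509 and 1660, and Krt14 was at 1218, 1263 and 439.1. Col1a1 and Col3a1 were chosen for the plot after their values were seen.

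Of 11 measured antigen presentation genes, most of them in the MHC class I pathway, 7 were higher and none lower, and the median log2 difference was 1.40 (interquartile range 0.79 to 1.76), above all 10000 random lists. Tap1 and Tap2, the subunits of the peptide transporter, were 6.22-fold and 4.09-fold higher. Psmb8 and Psmb9, catalytic subunits of the immunoproteasome, were 3.68-fold and 3.14-fold higher. The 7 include Cd74, the class II invariant chain, and without it 6 of 10 were higher with a median of 1.26. The MSC and fibroblast marker median of 0.61 stands beside this list too.

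All 20 measured genes of cholesterol biosynthesis had lower signals in co-culture, and 14 of them met the size rule. The median log2 difference was -1.54 (interquartile range -1.91 to -0.97), below all 10000 random lists. Fdps, which makes farnesyl diphosphate, was 5.87-fold lower, Nsdhl, a sterol dehydrogenase, was 5.21-fold lower, and Fdft1, the squalene synthase, was 4.61-fold lower. Lpin1, a phosphatidate phosphatase of lipid synthesis, was 6.05-fold lower. The MSC and fibroblast markers, at 0.61, lay in the opposite direction to this list. Whether RNA carried over from MSCs affected the list was not tested, and the opposite direction does not decide it.

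Proliferation genes had lower signals in co-culture, in part by at least 2-fold. All 27 measured G2/M and mitosis genes had lower signals, 12 of them by at least 2-fold, with a median log2 difference of -0.95 (interquartile range -1.28 to -0.67). Kif11, a motor of the mitotic spindle, was 4.00-fold lower, the cyclin Ccna2 was 2.87-fold lower, the mitotic kinase Plk1 was 2.71-fold lower and the kinesin Kif20a was 2.62-fold lower. All 26 measured G1/S and DNA replication genes were also at lower signals, and 4 met the size rule, namely Ccne2 at 2.79-fold, Tk1 at 2.48-fold, Rfc3 at 2.32-fold and Rrm2 at 2.00-fold. Their median log2 difference was -0.61, and the medians of these lists were both below all 10000 random lists. Fam83d, which acts at the mitotic spindle, was 4.71-fold lower. These lists too lay opposite to the MSC marker median of 0.61, which again does not decide whether carried-over MSC RNA affected them.

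Of 23 measured genes of the unfolded protein and amino acid stress responses, 7 were higher and none lower, with a median log2 difference of 0.47 at the percentile of 100 among random lists, beside 0.61 for the MSC markers. The transcription factor Ddit3 (CHOP) was 8.23-fold higher, Aldh1l2 4.51-fold, Atf3 4.21-fold and the pseudokinase Trib3 3.81-fold. Among 19 measured immediate early genes 6 were higher and none lower, with a median of 0.35 at percentile 98.2, and Fos was 4.25-fold, Spry4 2.83-fold and Klf6 2.61-fold higher. Among 16 measured p53 targets 4 were higher and 1 was lower, with a median of 0.15 at percentile 66.6. Gadd45a, Fas and Trp53inp1 were 8.41-fold, 8.36-fold and 3.21-fold higher, and Tnfrsf10b was 2.26-fold lower. For the stress, immediate early and p53 genes, co-culture cannot be told apart from isolation, which the labels give for the co-culture cells only. Outside the pathway lists, Txnip and Arrdc4, related arrestin-domain proteins that restrain glucose uptake, were 17.3-fold and 13.6-fold higher.

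Of 27 measured epithelial genes, which mark 4T1 identity, St14, an epithelial serine protease, was 2.04-fold higher and the basal keratin Krt14 2.77-fold lower, and the other 25 met no size rule. The median log2 difference was 0.34 at percentile 99.8, with Itgb4 at 0.87 and Cldn4 at 0.81. Among 12 measured mesenchymal transition genes, Sparc was 2.04-fold higher and none was lower, with a median of 0.31 at percentile 96.4, and Tnc, Twist1 and S100a4 had differences of -0.82, 0.76 and -0.76. Among 9 measured mammary luminal and secretory genes, 4 were higher and none lower, with a median of 0.77 at percentile 98.7, beside 0.61 for the MSC markers. The milk protein gene Csn3 was 15.1-fold higher, Xdh at least 4.74-fold, Btn1a1 3.25-fold and Aqp5 2.3-fold. The mammary median ranged from 0.08 to 0.98 over the alternative settings.

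Markers of other cell types differed unequally on the co-culture array. Among 10 measured MSC and fibroblast markers 2 were higher and none lower, with a median log2 difference of 0.61 at percentile 99.2. Bgn was at least 4.28-fold higher with a signal of 181.5, Postn was 2.35-fold higher with 1803 against 765.6 in regular medium, and Pdgfra and Col1a2 each had a difference of 0.89. The MSC marker median ranged from 0.02 to 0.73 over the alternative settings. Col1a1, Col3a1, Lum, Dcn, Thy1 and Mgp, chosen after their values were seen because MSCs usually make them in quantity, had co-culture signals of 41.9, 45.7, 43.8, 35.2, 6.7 and 38.9. Of the 3 measured smooth muscle and pericyte markers, Acta2 was at least 6.56-fold higher, Cspg4 at least 4.46-fold lower, and Mcam had a difference of -0.56. The 3 measured macrophage and leukocyte markers, Csf1r, Cd68 and Cd14, had differences of -0.48, 0.44 and 0.27. Egfl7, the measured endothelial marker, had a difference of 0.01, and Sox9 and Sp7, the measured osteoblast, chondrocyte and adipocyte genes, had 0.52 and -0.23.

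Secreted factors and their receptors gave mixed results. Among 13 measured chemokines and inflammatory cytokines, Ccl20 was at least 6.02-fold higher, Csf2 at least 3.57-fold higher and Cxcl10 2.53-fold higher, while Ccl2 was 3.36-fold lower. The median of this list was 0.54 at percentile 98.9, but it was -0.01 when only genes above the 80th percentile of signal were kept. Among 14 measured NF-kB targets, Irf1 was 2.59-fold, Relb 2.33-fold and Tnfaip2 2.15-fold higher and none was lower, with a median of -0.01 at percentile 41.9. Of 12 measured matrix proteases and inhibitors, 4 were lower and none higher. Mmp10 was 3.39-fold, Mmp3 2.78-fold, the urokinase receptor gene Plaur 2.47-fold and Timp1 2.01-fold lower, and the list median was -0.23 at percentile 3.86. None of 12 measured growth factors and receptors met the size rule, and their median was 0.51 at percentile 99.2, with Vegfc at 0.79 and Vegfa at 0.70. Among 17 measured TGF-beta response genes, Tgfb2 was 2.07-fold higher and Id1 2.05-fold lower, with a median of 0.11 at percentile 70.6.

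Metabolic and housekeeping lists lay nearer to 0. The 26 measured hypoxia and glycolysis genes had a median of -0.16 at percentile 3.13, with Pfkfb3 3.61-fold and Vldlr 3.60-fold higher and Ankrd37 3.86-fold lower. The 25 oxidative phosphorylation genes had a median of -0.08 at percentile 43.4, with Cox7c 2.87-fold and Uqcrfs1 2.42-fold lower. The 25 ribosome biogenesis and MYC target genes had a median of -0.19 at percentile 3.88, with Myc at 0.60 and Nop56 at -0.57. The 21 measured ribosomal protein genes had a median of -0.12 at percentile 29.6, which quantile normalization brought to 0.00, and another probe set of Rps9 differed in the opposite direction to the one used. The 14 NRF2 and oxidative stress genes had a median of 0.05 at percentile 61.5, with Pgd at -0.80 and Mt1 at 0.78. The 12 heat shock genes had a median of -0.25 at percentile 4.08, with Dnajb1 2.54-fold lower. The 12 stem cell and mammary progenitor genes had a median of -0.07 at percentile 25.6, with Lef1 3.42-fold and Klf4 2.53-fold higher. The 17 reference genes had a median of -0.17 at percentile 12.3, with the transferrin receptor gene Tfrc 2.34-fold lower.

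Among the remaining genes with the largest differences, Wnt9a, a Wnt ligand, was at least 10.0-fold higher. Rgs16, a regulator of G protein signalling, was 6.86-fold lower, Plek2 6.68-fold, Fgfbp1, a carrier of fibroblast growth factors, 5.35-fold, Scoc 4.84-fold and the decoy death receptor gene Tnfrsf23 4.72-fold. Krtap12-1 and Lce1h were at least 5.30-fold and 4.42-fold lower, from regular-medium signals of 224.9 and 187.4. In total 12 of the 25 fixed lists with a value lay outside the central 95% of random lists, where 1.25 would be expected from independent lists. Lists share genes, so they are not independent of each other.

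**Figure D2:**
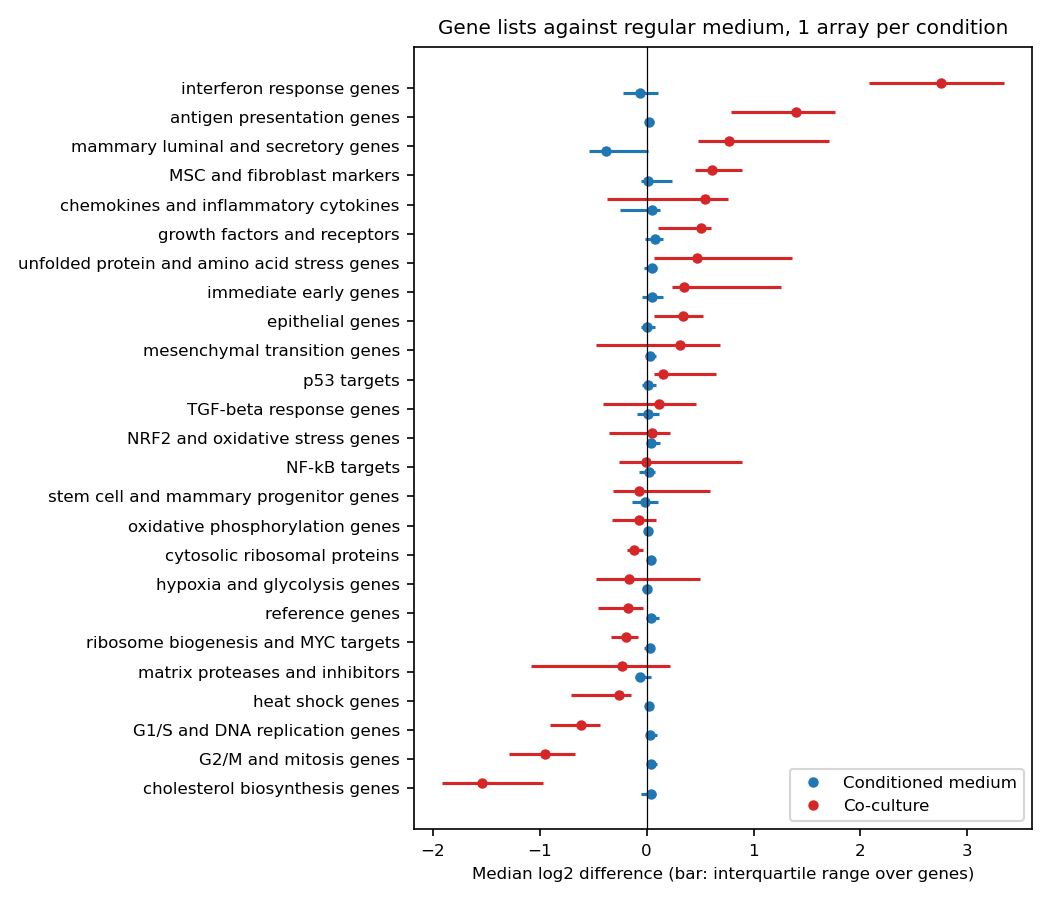
Median log2 difference from regular medium (horizontal axis) for the 25 gene lists with at least 5 measured members (vertical axis), in conditioned medium (blue) and co-culture (red), with bars for the interquartile range over genes. In co-culture the medians ran from -1.54 for cholesterol biosynthesis to 2.75 for the interferon response, and in conditioned medium the lowest was -0.38 for the mammary luminal list.

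Conditioned medium was compared with regular medium to see how the cells differed after exposure to factors secreted by MSCs without contact. Few genes differed by 2-fold, and the interferon, cholesterol and mitosis genes that differed in co-culture had medians near 0. The median log2 difference was -0.06 for the interferon response genes, 0.04 for cholesterol biosynthesis, 0.04 for G2/M and mitosis and 0.03 for G1/S and DNA replication, and no member of these lists met the size rule. Of 9152 genes with a bright signal on at least 1 of these 2 arrays, 10 were higher and 28 were lower. Quantile normalization gave 15 higher and 26 lower, so that 36.6% of the calls were higher in place of 26.3%.

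Fitm1, which acts in lipid droplet formation, was 4.15-fold higher, the aldo-keto reductase Akr1e1 3.64-fold, the phosphate transporter Slc34a2 3.13-fold, Pou5f2 2.75-fold, Tcl1b3 2.45-fold, Tmem102 2.29-fold, Olfm1 2.19-fold and Rpl39 2.02-fold. Pklr, the liver and red cell pyruvate kinase, was at least 3.73-fold higher and Acta2, smooth muscle actin, at least 3.70-fold higher. Among genes with lower signals, Wdr70 was 4.10-fold lower, although its other bright probe set had a log2 difference of -0.16, and Cphx3 was 4.01-fold lower. Cplx2, Ntrk2, Slc30a3, Serpinb6e, Trmt61b, Ccdc3, Myo15 and Rab38 were 2.92-fold, 2.77-fold, 2.63-fold, 2.62-fold, 2.47-fold, 2.41-fold, 2.38-fold and 2.35-fold lower. Krtap12-1, Hic1, a transcriptional repressor, and Cspg4 were at least 5.30-fold, 4.53-fold and 4.46-fold lower. Tcl1b3 was the only one of the higher genes with a signal above 1000, and Wdr70 the only one of these lower genes.

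Among the 25 fixed lists with a value, the mammary luminal and secretory genes lay outside the central 95% of random lists, where 1.25 lists would be expected. Their 9 measured members had a median log2 difference of -0.38 at percentile 0.255, with Csn3 at -1.04 and Aqp5 at -0.64, both at the floor in conditioned medium, Foxa1 at -0.54 and Stat5a at -0.49, and none met the size rule. Csn3 and Aqp5 reached 149.3 only in co-culture, so they count as measured through an array outside this comparison. This median ranged from -0.39 to 0.00 over the alternative settings, and the list lay inside the central 95% with a floor at the 60th percentile or without the signal filter. The MSC and fibroblast markers had a median of 0.01, with Pdgfra at 0.65, Bgn at 0.45 or more from the floor in regular medium, Col6a2 at -0.37 and Postn at 0.31. In the smooth muscle and pericyte list Acta2 was higher and Cspg4 lower, and in every other fixed list no measured member met the size rule. The chemokine list had a median of 0.05 with Ccl20 at 0.72 or more, again from the floor, and Cxcl5 at -0.58. The epithelial list had 0.01, and the mesenchymal transition list 0.04 with Tnc at -0.55. In the TGF-beta list Id2 had a difference of -0.22, and in the p53 list Btg2 had -0.49, each with another probe set that differed in the opposite direction. Unchanged arrays simulated with the probe set scatter of this comparison gave a median of 16 genes at least 2-fold apart and at most 27, against the 38 observed, and again hold no variation between cultures. Raising the floor to the 60th percentile of signal left 2 genes higher and 1 lower.

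**Figure D3:**
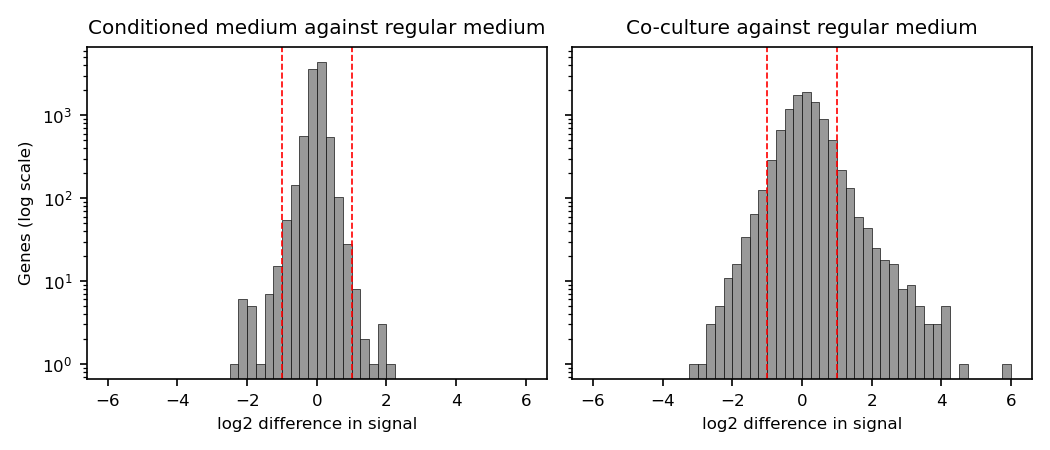
Histograms of log2 differences in signal (horizontal axis) of the 9452 measured genes, with the number of genes on a log scale (vertical axis) and dashed lines at 2-fold. Conditioned medium against regular medium (left) had a standard deviation across genes of 0.23 and co-culture against regular medium (right) 0.62.

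Co-culture was compared with conditioned medium to set contact beside exposure to secreted factors. Per the labels, only the co-culture cells were isolated from a mixed culture. Effects of contact, of isolation and of carried-over MSC RNA therefore cannot be told apart in this comparison. The interferon, cholesterol and mitosis genes differed as they did against regular medium. Usp18 was 46.3-fold higher in co-culture, Irgm2 25.6-fold, Igtp 21.5-fold, Arrdc4 17.6-fold and Txnip 17.5-fold, and Idi1 was 7.38-fold lower, Rgs16 7.07-fold, Fdps 5.73-fold, Nsdhl 5.39-fold and Lpin1 5.19-fold. Csn3 was at least 31.1-fold higher, Oas3 at least 12.7-fold and Cmpk2, an interferon-induced nucleotide kinase, at least 8.84-fold, while Lce1h, Asb4 and Pklr were at least 5.60-fold, 4.34-fold and 3.73-fold lower. Of 9350 genes with a bright signal on at least 1 of these arrays, 545 were higher and 243 lower.

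Of the 22 measured interferon response genes 20 were again higher, with a median of 3.06, and 7 of 11 antigen presentation genes were higher, with a median of 1.27. The cholesterol list had 15 of 20 members lower and a median of -1.57, the G2/M list 13 of 27 lower and a median of -0.97, and the G1/S list 4 of 26 lower and a median of -0.65. Stress response genes had a median of 0.39, epithelial genes 0.38, mammary luminal genes 0.97 (0.22 to 1.27 over the alternative settings) and immediate early genes 0.37. MSC and fibroblast markers had a median of 0.56 at percentile 98.2, with 1 of 10 higher, and their median ranged from 0.17 to 0.56. Matrix proteases and inhibitors had a median of -0.28 at percentile 2.25, which was 0.03 among genes above the 80th percentile of signal. The chemokine list had a median of 0.25 at percentile 77.0. In total 11 of the 25 lists lay outside the central 95% of random lists.

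Across the 9452 measured genes, log2 signals of the conditioned-medium and regular-medium arrays correlated with r = 0.991, and 85.5% of genes lay within 1.2-fold. The correlation of co-culture was 0.934 with regular medium and 0.935 with conditioned medium, with 40.9% and 40.1% of genes within 1.2-fold. Genes are not independent replicates, so these values describe the arrays. In co-culture 420 genes were higher than on both other arrays and 199 lower. Those counts share the co-culture array, and simulated unchanged arrays gave at most 50 and 19, while independent lists would share 32.0 and 6.77.

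Against the shared regular-medium array, 4 genes were higher in both conditioned medium and co-culture, 13 were lower in both and none was opposite. The 4 were Acta2, Akr1e1, Pou5f2 and Tmem102, and the 13 included Wdr70, Cphx3, Cspg4, Krtap12-1, Hic1 and Ntrk2. Apart from Wdr70, the 13 had regular-medium signals of only 149.8 to 224.9 and lay below 149.3 on both other arrays. They thus passed the signal filter only through the shared control array. Wdr70 had another bright probe set with a much smaller difference in conditioned medium, as given above. Independent lists would share 0.60 and 0.80 genes, and unchanged arrays against that control shared a median of 0 and 3 and at most 2 and 8. Simulations in this paragraph gave all 3 arrays the narrower scatter, an SD of 0.19 log2 per array, against 0.31 for the wider one. With the wider scatter, the counts that share the co-culture array reached 50 and 19, so the simulated counts here may be too low. The counts were 0 and 1 with a floor at the 60th percentile, where simulations gave at most 1 and 1, and 2 and 5 with the mean over probe sets, where they gave at most 2 and 4. Across the 9452 measured genes the differences from regular medium correlated with Pearson's r = 0.18 and Spearman's rho = 0.15. Simulated unchanged arrays gave r = 0.50, but with equal scatter on all arrays. The observed differences had unequal standard deviations, 0.23 and 0.62, so these r values cannot be set against each other. The covariance of the differences was 0.0254 against a simulated 0.0178, a difference of 0.00766. With the 60th-percentile floor it was 0.0151 against 0.0142, inside the simulated range. With the 80th-percentile filter it was 0.0081 against 0.0085, also inside that range, and 0 and 1 genes were shared, against at most 1 and 0 simulated. Without the signal filter the counts were 21 and 76, against at most 8 and 18 simulated. The 3-fold rule gave 2 and 4 against at most 1 and 2, and the 1.5-fold rule 39 and 44 against at most 19 and 31. An excess over the narrower scatter was thus seen under some settings and not under others. As the control array could not be split, part of it may come from the shared control.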

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

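All alternatives were chosen before the data were examined, apart from the lists added later. No paired analysis was possible because each group has 1 array. Over 897 alternative values of gene list medians, 887 stayed the same by the measure used, 6 moved and 4 reversed, and of 4046 alternative values of named gene differences 207 moved and 0 reversed. The interferon median in co-culture against regular medium ranged from 2.17 to 2.95 over the settings, cholesterol from -1.63 to -1.11, G2/M from -1.01 to -0.81 and epithelial genes from 0.20 to 0.40. Dividing by the trimmed mean or centring on bright probe sets moved no count by over 1.5 times. Calls in conditioned medium lie mostly close to the 149.3 level, where the signal limits what can be seen.

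Raising the floor to the 60th percentile gave 2 genes higher and 1 lower in conditioned medium, 0 higher and 1 lower in both conditions, a covariance of 0.0151 and 0 lists outside in conditioned medium. A floor at the 20th percentile and a pseudocount of 16 each gave 2 such lists. Keeping genes above the 80th percentile gave 1 higher and 1 lower in conditioned medium, 303 and 132 in co-culture against regular medium, 282 and 141 against conditioned medium, 0 and 1 in both conditions, and a covariance of 0.0081. That filter also reversed the co-culture chemokine median against regular medium, to -0.0117, the protease median against conditioned medium, to 0.0298, and the dissociation gene median in conditioned medium, to -0.0134. The latter was also -0.0134 with plain probe sets alone. Dropping the filter gave 59 and 200 in conditioned medium, 429 lower in co-culture against regular medium, 21 and 76 in both conditions, r = 0.31, a covariance of 0.0442 and 0 lists outside in conditioned medium. The mean over probe sets gave 15 lower in conditioned medium, 363 higher in co-culture against regular medium, and 2 and 5 in both conditions. A 3-fold rule gave 5 and 12 in conditioned medium, 164 and 58 in co-culture against regular medium, 177 and 56 against conditioned medium, and 2 and 4 in both conditions. A 1.5-fold rule gave 69 and 134, 1586 and 926, 1579 and 930, and 39 and 44 in the same order. The size rules and the filters change counts by their construction, and for the other settings the cause was not tested.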

Other observations

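Gene groups chosen after the values were seen filled out the co-culture picture. Among 17 measured fatty acid synthesis genes, 6 were lower against regular medium and none higher, with a median log2 difference of -0.65. Aacs, which activates acetoacetate for lipid synthesis, was 4.18-fold lower, the desaturases Scd2 and Fads2 3.12-fold and 2.97-fold. Among 31 measured lysosome and V-ATPase genes 6 were higher and none lower, with a median of 0.51. The lysosomal membrane protein gene Scarb2 was 4.00-fold, the cholesterol exporter Npc1 2.80-fold, Atp6v0d1 2.54-fold and Sgsh 2.42-fold higher. All 9 measured immunity-related and guanylate-binding GTPases were higher, with a median of 2.39, and Gbp7 was 12.5-fold higher. Among 16 measured targets of FOXO and MondoA, transcription factors that respond to growth signals and glucose, 7 were higher and 1 lower, with a median of 0.68 in co-culture and 0.12 in conditioned medium. These lists were chosen because of such values, so their medians are not independent evidence. The class II genes Ciita, H2-Aa, H2-Ab1 and H2-Eb1 had co-culture signals of 30.7, 36.9, 29.6 and 14.7, all below the floor, while Cd74, of the same pathway, was 1.54 log2 higher than in regular medium and 1.27 higher than in conditioned medium. H2-DMa was 1.21 log2 higher than in regular medium but 0.35 higher than in conditioned medium, where it was already at 0.86. The ligand genes Ifnb1, Ifna4 and Ifng had co-culture signals of 34.8, 33.3 and 7.2, each below the floor.

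Explanations were tested for the MSC markers, the number of genes and the interferon genes. The tests of carried-over RNA and of handling for the interferon genes, and the test of class II genes, were chosen after the values were seen, and the scatter test was split by condition after the counts were seen.

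MSC and fibroblast markers were higher in co-culture than in conditioned medium by a median of 0.557, which meets the condition set beforehand, a median above 0.26, for MSC RNA carried over with the isolated cells, but it was 0.17 without the signal filter, which does not meet it. A further condition, added after the values were seen, was not met, since none of the 6 genes Col1a1, Col3a1, Lum, Dcn, Thy1 and Mgp reached 149.3. Because it was chosen on seen values, and Col1a1, Lum, Dcn and Mgp were above their regular-medium signals, it does not count against carry-over. Of the 28 named markers 19 were below that level in co-culture, and 7 of the 10 measured were already above it in regular medium. A lower share of 4T1 cells would lower the epithelial genes, but their median was 0.339 higher (bootstrap over genes 0.116 to 0.472). That is the direction set beforehand as counting against a lower share, and no net lowering was seen. The test cannot exclude a lower share, because a rise of these genes within the 4T1 cells could hide it. The bootstrap covers genes of 1 pair of arrays and not the share of cells. A small carry-over and expression by the 4T1 cells themselves cannot be told apart, because the labels give no measure of purity after isolation.

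The number of genes apart in co-culture was 805, and the highest scatter simulation gave 214. In conditioned medium it was 38, and the highest simulation gave 27. The simulations hold only the scatter between probe sets of a gene, so with 1 array per condition, scatter that includes variation between cultures cannot be told apart from an effect of either condition. Quantile normalization gave 811 genes in co-culture, which argues against a difference in signal distribution left by the scaling.

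Interferon response genes may reflect a response of the 4T1 cells in co-culture. Carried-over MSC RNA as their source stays open, since the median gain in signal of the measured MSC markers was 0.320 of that of the measured interferon genes, and no array of MSCs alone was among the 3 used here. Col1a1, Col3a1, Lum, Dcn, Thy1 and Mgp had signals of at most 45.7 in co-culture, but how bright they and the interferon genes were in these MSCs is unknown. The same ratio over all named genes was 0.0277. The smallest share of MSC RNA that could give the largest interferon gene gain, 5928.5, was 13.5%, if its MSC signal equalled the brightest of any array, 43954.2. The 13.5% is not an estimate of the share present. Both values were tried after the data were seen, each first read against carry-over and then dropped as not deciding it. Handling during isolation stays open, since the dissociation response genes had a median of 0.363 against conditioned medium, with 6 of 9 measured members above 0 and 3 below. A response of the type I interferon kind met its condition, but that was written after the values were seen, so meeting it lends no support. The highest co-culture signal among Ciita, H2-Aa, H2-Ab1 and H2-Eb1, which interferon gamma usually induces, was 36.9. The type I reading was further weakened once Cd74 was seen to be higher, so the interferon type cannot be told apart. Culture density and the source of any ligand were not tested.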
